A study of Mus musculus with 13 samples.

How the data were processed

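The mark measured was 5-hydroxymethylcytosine (5hmC), the oxidised form of 5-methylcytosine that TET enzymes make, in DNA of mouse knee cartilage. The method, per the labels' protocols, was reduced representation hydroxymethylation profiling (RRHP). DNA was cut at CCGG sites with MspI, adapters were ligated, and a glucosyltransferase reaction put glucose on 5hmC at the ligated ends. Glucose blocks MspI, so a repeated digest destroys the fragments without 5hmC at their ends, and the surviving fragments were amplified in 15 PCR cycles. The labels list 13 samples, which are 4 groups of 3 and 1 background control made without the glucosyltransferase. The groups are wild-type (WT, Tet1+/+) and mutant (MUT, labelled TET-/-) mice, each with sham surgery or with destabilisation of the medial meniscus (DMM), an operation that makes the knee joint unstable and leads to osteoarthritis. All samples were taken 6 weeks after surgery from male mice of the mixed strain B6;129S4. Their age is given as 3 to 4 months in the series' design text and as 4 to 6 months in the treatment protocol. The MUT sham libraries and the background control are not analysed here, so no background level was subtracted and the effect of genotype without surgery was not tested.

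Per the submitters' processing notes, the authors used bcl2fastq 2.20.0, Trim Galore 0.5.0, HISAT2 2.1.0, SAMtools and bedtools with the mouse genome mm10. The program that called regions is not given in the sources used here. The authors deposited 3 tables, 1 per comparison, named WT DMM against WT sham, MUT DMM against WT DMM and MUT DMM against WT sham. Each entry is a region built from windows of 200 bases in steps of 20 bases, and the largest window p-value in every table was 0.0001, so regions without a difference are not listed. The median region was 260 to 280 bases long. Per the file headers, the authors' p-values and adjusted p-values belong to the whole region and to its best window. The other columns hold the deposited normalized count of each library, 3 per group joined in one cell, the mean signal of each group (coverage scaled per library by a factor not given in the sources used here), and the log2 fold change that the authors took from the group means with no pseudocount. The means equalled the means of the 3 joined values in 100% of regions. The tables had passed through a spreadsheet, which left an error in place of the log2 fold change in 15289 regions of MUT DMM against WT sham whose MUT DMM mean was 0, and turned 40 to 92 gene names per table into dates. Fold changes were therefore recomputed from the means, and gene names were taken from coordinates.

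The values of a library were whole multiples of a single step in 99.9954% to 100% of regions, within a tolerance of 0.02 normalized counts. A step was therefore read as 1 sequenced read, and the reads in the listed regions were recovered. The count models of the plan were not run, because the deposited values are joined, already normalized and listed only for regions that had passed the authors' p-value. In the table of WT DMM against WT sham the sham libraries held 1400953, 563233 and 2187392 reads in the listed regions, and the WT DMM libraries held 4726, 436852 and 925241. In the same order, the values in MUT DMM against WT sham were 4720342, 2136912 and 7860851 reads for sham. The columns carry no replicate number, so libraries are named by their place in the joined cell. The first-listed WT DMM library was nearly empty, and 1 of its reads was worth 15.7 normalized counts in the first table and 9.56 in the second. A pair of the MUT DMM entries held identical values in every region of both tables, and their reads equalled those of a single library in 100% of the 1863 regions with shared bounds. That library, of 5889464 reads in MUT DMM against WT DMM, was counted once in every mean ± SD here, which leaves 2 distinct MUT DMM libraries, the other with 407929 reads. In all, the tables hold 8 distinct libraries. The design text calls the replicates biological but does not say that each is a separate animal, and the protocol puts the control on the opposite leg, so limma's p-values measure the spread between these libraries and not between animals. The authors' test is not known, and its p-values were small at some regions read mainly in 1 library of a group. PCR reads carried no molecular identifiers, so binomial intervals cover counting error only, and neighbouring regions are not independent.

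A changed region is one with the authors' adjusted p under 0.05, a choice made before the data were examined together with the groups, the gene lists, the named-gene rule and the settings varied. Shares of higher regions were given with exact (Clopper-Pearson) 95% intervals and exact two-sided binomial tests across regions. Gene positions came from the RefSeq table of assembly GRCm38.p6, which has the coordinates of mm10. It gives gene bounds without strand or exons, so promoters, exons and introns were not told apart, the share of regions inside gene bodies was compared by Fisher's exact test instead, and a gene was counted as holding a region within its body or 1 kb of either end. There were 14 gene lists with 431 genes, all of them matched: cartilage matrix, matrix proteases and inhibitors, hypertrophy and ossification, chondrogenic transcription factors, Wnt signalling, TGF-beta and BMP signalling, insulin, IGF and mTOR signalling, inflammatory and NF-kB signalling, DNA methylation and hydroxymethylation machinery, and markers of haematopoietic, skeletal muscle, endothelial, adipocyte, and fibroblast and synovial lining cells. For each list and direction the number of genes with a changed region was compared with 10000 random lists of the same size, each gene replaced by one of the 100 nearest in length on either side. The lists were not matched on the number of CCGG sites, the only places RRHP reads, so an excess of genes with regions is not separated from a richness in such sites. The tests were two-sided permutation tests, with Benjamini-Hochberg adjustment over the 28 tests of a comparison. On simulated lists of long genes without an effect, 6% were called with length matching and 26.0% without it, and 61% of lists with 15 of 30 genes given a region were called. Named genes were Tet1, Tet2 and Tet3, the 2 members of each list with the most changed regions, the 4 genes with the most higher and the most lower regions, and the 3 regions of smallest adjusted p in each direction. Where a gene is given with levels, they are those of its changed region of smallest adjusted p.

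Regions of a pair of tables were called shared when they overlapped by at least 1 base. Directions were compared by Fisher's exact test, and the number of pairs was set beside 100 shuffles of region positions. Unchanged groups were also simulated, the shared group among them. The simulation used the read step of each library, sham levels and a small fixed spread between libraries. It paired the simulated regions with the largest fold changes and not regions chosen by p. After the data had been seen, a limma 3.58.1 fit (R 4.3.3) on log2(normalized count + 1) over the listed regions was added, with the repeated library once and Benjamini-Hochberg adjustment. The listed regions had passed the authors' p-value in the same libraries, so the adjusted p-values of this fit are not valid error rates. Tested on simulated data with 200 of the listed regions raised 4-fold in the first-named group, the fit recovered 23.5% in WT DMM against WT sham with 107 unchanged regions called, and 57.5% with 3 unchanged regions called when the near-empty library was left out. For MUT DMM against WT DMM it recovered 26.0%, and 12.5% without that library, with 0 unchanged regions called in either. For MUT DMM against WT sham it recovered 30.5% with 1 unchanged region called. Decreases were not simulated, so the recovery of lower regions was not tested. Alternatives were an adjusted p under 0.01, a minimum log2 fold change of 1, merging within 100 bases, leaving out the 25% of regions with the lowest level, and leaving out each library. Others were wider gene margins, unmatched random lists, wider overlap, and regions that separate all libraries. For the gene lists, separation was taken without the near-empty library. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.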

Results

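Maps of 5hmC in mouse knee cartilage were compared in 3 tables of regions: wild-type knees after DMM against wild-type sham knees, mutant knees after DMM against wild-type knees after DMM, and mutant knees after DMM against wild-type sham knees. The series' title asks about the role of TET1, an enzyme that oxidises 5-methylcytosine to 5hmC, in osteoarthritis. Levels are normalized read counts per region and are comparable within a table only, because a library was scaled differently in each. WT sham and WT DMM had 3 libraries each and MUT DMM had 2 distinct libraries, since a pair of its 3 entries was identical. Depth differed widely. In the regions of MUT DMM against WT DMM, the deeper MUT DMM library held 5889464 reads and the shallower 407929, while the WT DMM libraries held 52972, 1961515 and 2899132. The first-listed WT DMM library was at 0 in 95.8% of the regions of WT DMM against WT sham and in 64.4% of those of MUT DMM against WT DMM.

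**Figure D1:**
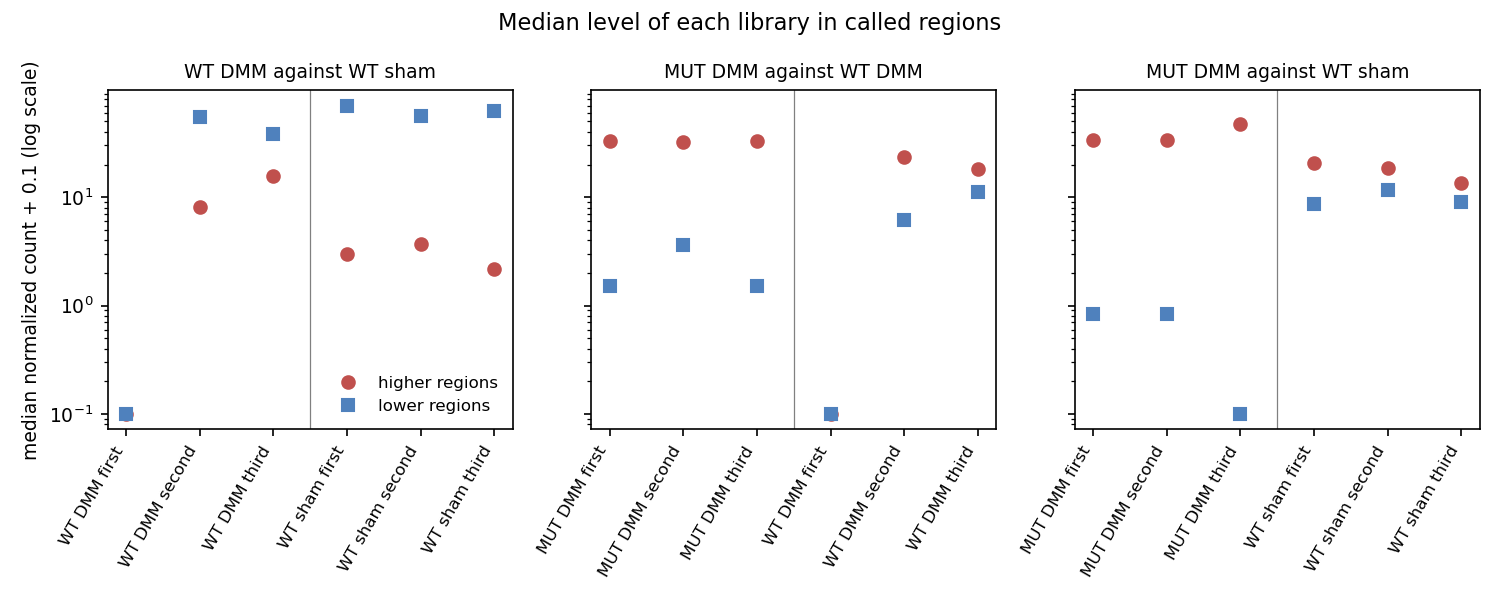
Median normalized count of each library (log axis, with 0.1 added so that 0 can be drawn) over the regions called higher (circles) and lower (squares) in each comparison, with libraries in the order of the tables. The first-listed WT DMM library had a median of 0 in both of its tables, and one library stands in 2 of the 3 MUT DMM places in the middle and right panels.

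The targeted gene itself was examined first. Tet1 lies on chromosome 10 from 62804570 to 62887469 (mm10), and the part removed in the mutant is not given in the sources used here, so 5hmC at the locus is no check of the genotype labels. Within 5 kb of Tet1, WT DMM against WT sham had 3 regions, all higher, MUT DMM against WT DMM had 4, all lower, and MUT DMM against WT sham had 4, all lower. Of all changed regions in these comparisons, 93.4%, 34.6% and 43.5% were higher, in the same order, so so few regions show no pattern particular to Tet1. The Tet1 region at 62840281 to 62840660 stood at 2.12 ± 2.02 (SD, n = 2) normalized counts in MUT DMM and 8.22 ± 7.20 (n = 3) in WT DMM. That difference was smaller than the spread of the WT DMM libraries, which had 0, 15 and 22 reads, the 0 in the near-empty one. The MUT DMM libraries had 3 and 1 reads. Against sham, on the scale of that table, the same region stood at 5.83 ± 5.12 (n = 2) in MUT DMM and 13.7 ± 4.20 (n = 3) in WT sham. In the authors' deposited table its adjusted p was 1.34e-05 against WT DMM and 0.000727 against WT sham.

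In wild-type cartilage, regions with more 5hmC after DMM far outnumbered those with less: 40407 of 43240 changed regions were higher than in sham (93.4%, exact 95% interval 93.2 to 93.7). This share depended on level. Where the sham mean was at most 4.22 normalized counts 100% were higher, and above that 73.8% were. In this comparison 1 read of a WT DMM library was worth 1.04 to 15.7 normalized counts, so low sham levels left little room for a lower call. The cause of the dependence was not tested. Sox5, a long gene whose product drives the chondrocyte program with Sox6 and Sox9, held 19 higher regions, and Nfia, another long gene, held 13, with none lower. Runx2 and Mef2c, transcription factors of chondrocyte hypertrophy, held 8 and 6 higher regions and none lower, and Adam12, a metalloprotease, held 8. The median higher region had 7.62 normalized counts after DMM and 2.77 in sham, and the median of the folds of single regions was 2.67. For the 2833 lower regions the medians were 33.8 after DMM and 61.8 in sham, with a median fold of 1.80.

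Matrix and protease genes gave examples at these low levels. Col9a1, a chain of the type IX collagen of cartilage fibrils, had 2 higher regions, with 8.46 ± 8.04 (n = 3) after DMM against 2.18 ± 0.811 (n = 3) in sham. Vcan, the proteoglycan versican, also had 2, with 6.10 ± 8.35 against 2.05 ± 0.753. Adam12 showed 8.37 ± 10.2 against 2.05 ± 0.753, and Adamts17 had 6 higher and 1 lower region. Runx2 showed 10.9 ± 17.7 against 2.33 ± 0.480, and Nfia 9.31 ± 8.08 against 2.14 ± 0.425. At Runx2 and Vcan the higher level came from the third-listed WT DMM library alone, without which the means were 0.665 and 1.335, below sham. The named regions of Bmp6, Uhrf2, Fli1, Erg, Dlg2 and Zfp978 turned in the same way, and the lower one of Ror2 turned without the near-empty library (94.7 against 92.1). In the Wnt list, the receptor genes Ror1 and Ror2 held 6 higher regions and 3 higher with 3 lower, respectively. Bmp6, a growth factor of the BMP family, held 5 higher and 1 lower, and Ltbp1, which binds latent TGF-beta, held 5 higher. Rptor, the mTOR partner raptor, held 6 higher regions and none lower, and Mtor held 3 higher and 2 lower. Il1r1, the interleukin-1 receptor, showed 27.0 ± 14.0 (n = 3) after DMM and 14.0 ± 1.97 (n = 3) in sham. The WT DMM libraries had 1, 17 and 41 reads there, so the level of the near-empty library rested on 1 read. Nfkb1 held 2 higher and 1 lower region. Among genes of the methylation machinery, Uhrf2 held 3 higher regions, Zbtb38 held 2, Tet3 held 1 lower region and Tet2 held none. Genes used as markers of other cell types were among the calls too: Erg held 5 higher regions, Neb 5, Ttn 4 with 1 lower, Fli1 4, Flt1 3 with 1 lower, Ebf1 3 with 1 lower, and Pparg, Dpp4 and Tnxb 2 each, with 1 in Lep.

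The genes with the most higher regions were very long genes of neuronal cell contacts, Cntnap2 with 33 (0 lower), Dlg2 with 31 (1 lower) and Lsamp with 28 (0 lower), and the zinc finger gene Zfp978 with 30 (2 lower), which has near-identical neighbours and is therefore uncertain. The most lower regions lay in Tmem267 (7, 0 higher), Ahnak2 (6, 0 higher), a (4, 3 higher) and Ndst1 (4, 1 higher). The count of Tmem267 is uncertain, because its regions starting at 119491841 and 119605921 had nearly equal reads and may be copies of each other. Sham had 343, 82 and 517 reads at the former and 354, 80 and 506 at the latter. WT DMM had 3, 32 and 30 reads at the former and 3, 32 and 29 at the latter. At Tmem267 the level was 24.3 ± 6.45 (n = 3) after DMM and 102 ± 82.0 (n = 3) in sham, and at Ahnak2, which encodes a giant scaffold protein, 38.2 ± 19.6 against 168 ± 99.5. The higher regions of smallest adjusted p lay on chromosome 13 from 53294801 to 53295100 outside genes, in Gm4740 and in Gp6. Gp6 encodes the platelet collagen receptor. The region on chromosome 13 stood at 26.8 ± 10.1 (n = 3) after DMM and 13.8 ± 2.47 (n = 3) in sham. In each of these higher regions the near-empty WT DMM library had 1 read. The corresponding lower regions lay on chromosomes 13 and 14 outside genes and in Rtl4 on chromosome X, where all 3 WT DMM libraries were at 0 and the sham libraries averaged 26.3 ± 38.3. The first-listed sham library carried all 3 of these lower regions, with 115.3, 68.5 and 70.5 normalized counts on chromosomes 13, 14 and X, where no other sham library exceeded 5.72.

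No gene list held more or fewer genes with changed regions than length-matched lists in this comparison. The smallest p belonged to endothelial markers, of which 6 of 20 genes, among them Pecam1 and Cdh5, held a lower region where matched lists gave 1.36 (permutation p = 0.00260, adjusted p = 0.0728). Wnt signalling followed, with 10 of 48 genes lower against 4.03 (adjusted p = 0.157). Higher regions lay in 12 of 30 cartilage matrix genes, 12 of 33 protease genes, 14 of 30 hypertrophy genes and 21 of 28 chondrogenic transcription factors, with 2, 6, 4 and 6 genes holding lower ones. They lay in 28 of the 48 Wnt genes, 19 of 43 TGF-beta and BMP genes (6 lower), 19 of 39 insulin, IGF and mTOR genes (4 lower) and 16 of 46 inflammatory genes (3 lower). Of the methylation machinery, 7 of 22 genes held a higher and 2 a lower region. Among cell markers, the genes with higher regions were 14 of 32 haematopoietic (4 lower), 6 of 28 skeletal muscle (4 lower), 13 of 20 endothelial, 4 of 15 adipocyte (0 lower) and 9 of 20 fibroblast and synovial lining (2 lower). Higher regions lay in gene bodies less often than lower ones, 49.7% against 58.5% (Fisher's exact p = 2.43e-19).

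The spread between libraries was large relative to these differences. All 3 WT DMM libraries lay beyond all 3 sham libraries, in the called direction, in 1172 regions, which are 1.07% of the higher and 26.2% of the lower calls. The near-empty library was at 0 in 97.5004% of the higher regions, which therefore had no way to separate. Without it 35342 regions separated the groups, 34465 of them higher (85.3% of the higher calls) and 877 lower (31.0%). Chance gives 10% of calls with that library and 20% without it, before any choice of regions by p. Without the third-listed WT DMM library 69.3% of the higher calls kept their direction. Limma, which weighs the spread between libraries, called 7 regions, all lower (361 at unadjusted p under 0.05), and without the near-empty library 32922 higher and 811 lower. In every comparison limma saw only regions already chosen for a difference between the same libraries, so its counts are no independent check of the calls.

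**Figure D2:**
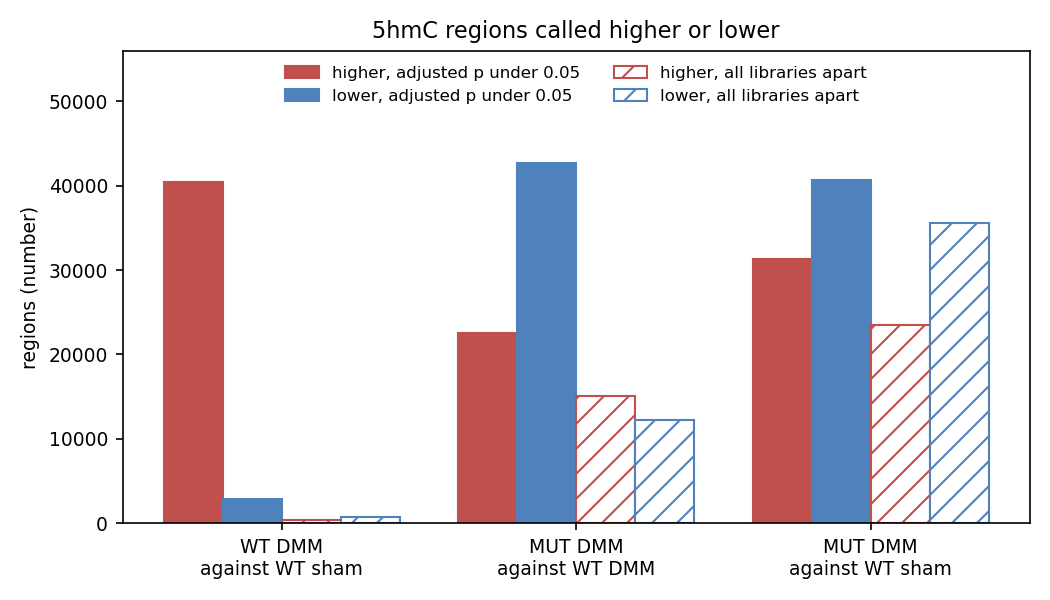
Number of regions called higher (red) or lower (blue) in each comparison, at the authors' adjusted p under 0.05 (filled bars) and among them those in which every distinct library of one group lay beyond every library of the other (hatched bars). WT DMM against WT sham falls from 40407 higher and 2833 lower to 431 and 741, and MUT DMM against WT sham from 31290 and 40684 to 23534 and 35584.

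After the operation, mutant cartilage had less 5hmC than wild-type cartilage in most changed regions: 42678 of 65249 were lower and 22571 were higher (34.6% higher, exact 95% interval 34.2 to 35.0). The lower majority lay in regions of low WT DMM level. Where the WT DMM mean was at most 5.2 normalized counts 15.6% were higher, and from 5.2 to 10.06 17.7% were. From 10.06 to 19.12 the share was 54.0%, and above that 51.0%. The cause of this dependence on level was not tested. Among the list members with the most changed regions, Sox5 held 20 lower regions and 2 higher, Zbtb20 held 11 and 4, and Col27a1, a fibrillar collagen of cartilage, held 10 and 1. Igf1r, the receptor for IGF-1, held 10 lower and 2 higher regions, Prkca, a protein kinase C, held 10 and 5, and Tcf7l1, a transcription factor of the Wnt pathway, held 9 and 3. With the repeated library counted once, the median lower region stood at 2.36 normalized counts in MUT DMM and 7.49 in WT DMM, and the median higher region at 32.6 and 15.7.

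At the regions of smallest adjusted p in Col27a1, Sox5, Igf1r, Acvr1, Tet3 and Col9a3, the level of the near-empty WT DMM library came from 1 to 4 reads and that of the shallower MUT DMM library from 0 to 6. Col27a1 showed 6.59 ± 0.728 (n = 2) in MUT DMM and 21.9 ± 6.42 (n = 3) in WT DMM, 3.32-fold lower. Sox5 showed 8.59 ± 2.09 against 23.8 ± 6.23 on chromosome 6 from 144782141 to 144782500, and Igf1r 9.40 ± 3.25 against 27.6 ± 7.51. Acvr1, a BMP receptor, held 7 lower and 4 higher regions, with 13.1 ± 1.62 against 29.8 ± 2.70. Tet3, another TET enzyme, held 5 lower regions and no higher one, with 21.2 ± 0.191 (n = 2) against 46.0 ± 11.4 (n = 3), and Tet2 held 4 lower. Col9a3 held 2 lower regions and 1 higher, with 0.585 ± 0.827 against 8.89 ± 1.88. Runx2 and Ank differed by less than the spread between the WT DMM libraries, of which the near-empty one was at 0. Runx2 (5 lower, 2 higher) showed 11.6 ± 3.77 against 20.6 ± 18.1, and Ank (7 lower, 1 higher), a pyrophosphate transporter that limits mineral deposits, 16.9 ± 6.31 against 28.4 ± 25.1. Further lower and higher counts were 7 and 5 in the procollagen protease gene Adamts2, 4 and 3 in Adamts17, 6 and 4 in Tcf7l2, 7 and 3 in Ltbp1, 5 and 0 in Il6ra, 2 and 3 in Nfkb1, and 4 and 1 in the DNA methyltransferase gene Dnmt3a. Without the third-listed WT DMM library the lower regions of smallest adjusted p in Ltbp1 (4.84 against 4.515), Il6ra (2.01 against 1.505) and Acsl1 (2.245 against 1.88) turned higher, and that in Il6ra also without the deeper MUT DMM library (3.55 against 3.24). Of the cell marker genes, Erg held 8 lower and 1 higher, Flt1 7 and 3, Ttn 7 and 3, Runx3 6 and 2, Pax5 3 and 6, Clic5 5 and 1, Col5a1 4 and 1, Acsl1 3 and 1, and Cebpa 0 and 2.

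The most higher regions lay in Fto (21 higher, 11 lower), Flg2 (20 and 0), Camta1 (18 and 11) and Gm37013 (14 and 15). The most lower ones lay in Zfp993 (34 lower, 10 higher), Zfp978 (28 and 13), Sfi1 (26 and 2) and Wwox (23 and 1). Zfp993, Zfp978, Sfi1 and Gm37013 have near-identical copies or overlap other genes, so their counts are uncertain. Flg2, a filaggrin gene of the epidermis, stood at 59.4 ± 6.53 (n = 2) in MUT DMM and 27.7 ± 9.42 (n = 3) in WT DMM. The smallest adjusted p values for higher regions were in Stk3, a Hippo pathway kinase (28.0 ± 5.58 against 4.00 ± 4.97), in Cxadr (33.0 ± 3.62 against 11.6 ± 6.75) and outside genes on chromosome 14. Those for lower regions were in Nipsnap1, Usp24 and Plec, with 2.34 ± 3.31 against 15.8 ± 5.91 at Plec, which encodes the cytoskeletal linker plectin.

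More Wnt signalling genes than in length-matched lists held a region that was higher in MUT DMM: 41 of 48 against 21.9 (permutation p = 0.0002, the smallest possible with 10000 lists, adjusted p = 0.00560). Members included the ligand genes Wnt5a (3 higher, 1 lower) and Wnt7b (3 and 6), the receptor gene Fzd7 (3 and 0) and the inhibitor gene Frzb (2 and 0). TGF-beta and BMP signalling followed with 30 of 43 genes against 19.6 (adjusted p = 0.0196), among them Bambi (2 higher, 0 lower), a decoy receptor, and Ltbp3 (3 and 1). Among regions that separate the libraries when the near-empty library is left out, this call was lost and the Wnt call remained. For lower regions neither list passed, with 29 of 48 and 29 of 43 genes. Skeletal muscle markers did not pass either, with lower regions in 6 of 28 genes against 12.0 (adjusted p = 0.0840) and higher ones in 13. In the order higher then lower, the other lists had 9 and 15 of 30 cartilage matrix genes, 17 and 15 of 33 protease genes, 15 and 16 of 30 hypertrophy genes, and 20 and 24 of 28 chondrogenic transcription factors. There were 24 and 26 of 39 insulin, IGF and mTOR genes, 20 and 25 of 46 inflammatory genes, and 9 and 16 of 22 genes of the methylation machinery. Marker genes were 11 and 16 of 32 haematopoietic, 8 and 11 of 20 endothelial, 4 and 5 of 15 adipocyte, and 4 and 11 of 20 fibroblast and synovial lining genes. None of these passed, the smallest adjusted p among them being 0.159. Higher regions lay in gene bodies more often than lower ones, 57.4% against 53.5% (Fisher's exact p = 9.08e-22).

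**Figure D3:**
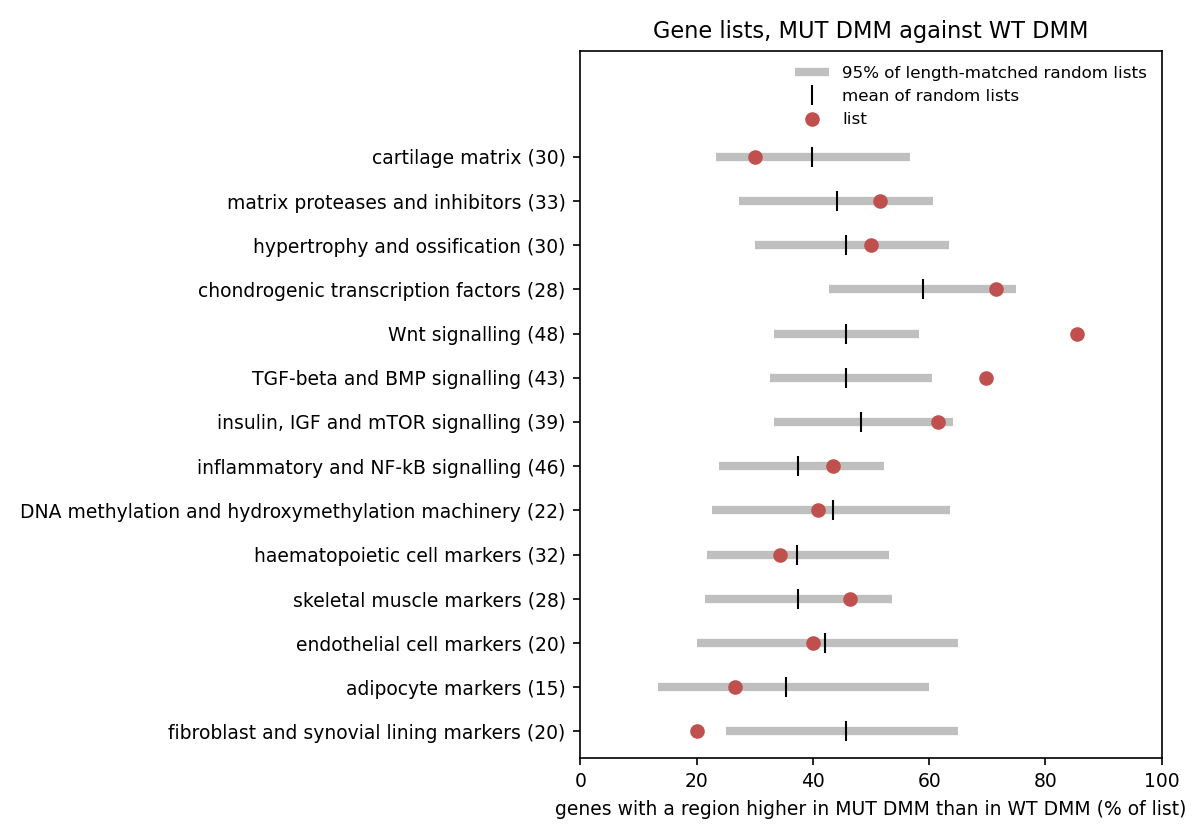
Percent of the genes of each list (number of genes in brackets) with a region higher in MUT DMM than in WT DMM (red points), beside the mean (black ticks) and the central 95% (grey bars) of 10000 random lists matched on gene length. Wnt signalling (41 of 48 genes) and TGF-beta and BMP signalling (30 of 43) lie above their bars.

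Without the third-listed WT DMM library 53.5% of the 65249 regions were higher in MUT DMM, but the WT DMM mean then rested on the second-listed and the near-empty library. All distinct libraries separated the groups in the called direction in 27328 regions, 15119 higher and 12209 lower, a count held down by the near-empty library, which was at 0 in 61.8% of the lower regions. Without that library 50796 regions separated the groups, which were 70.5% of the higher and 81.7% of the lower calls. Chance gives 20% of calls with that library and 33.3% without it, before any choice of regions by p. Limma called 0 regions (2869 at unadjusted p under 0.05), and without the near-empty library 3854 higher and 6519 lower.

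A set of regions was read in both MUT DMM libraries and in no WT DMM library. There were 125 such regions, and 47 of them (37.6%) lay in 5 bins of 5 Mb that held 5 or more each. The fullest was chromosome 8 from 85 to 90 Mb with 15, followed by chromosome 8 from 90 to 95 Mb with 13 and chromosome 2 from 155 to 160 Mb with 9. None of these bins is on chromosome 10, where Tet1 lies. At chromosome 8 from 86231741 to 86232360 the MUT DMM libraries had 450 and 32 reads, and the sham libraries had 2, 0 and 0. Fto, an RNA demethylase gene at 91 Mb of chromosome 8, gave a similar case at 91430961 to 91431380, with 233 and 24 reads in the MUT DMM libraries and 0, 2 and 9 in the WT DMM libraries. In the overlapping region of MUT DMM against WT sham, the sham libraries had 27, 12 and 28 reads.

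**Figure D4:**
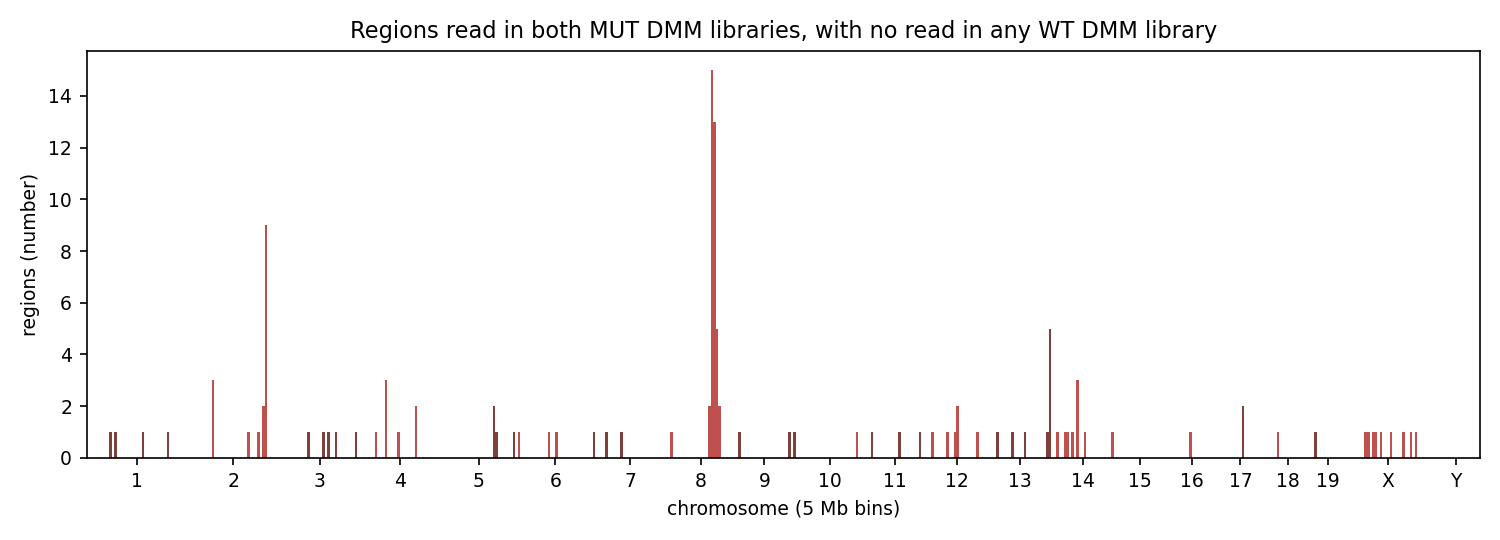
Number of regions per 5 Mb bin along the chromosomes that were called higher in MUT DMM than in WT DMM, had reads in both distinct MUT DMM libraries and had no read in any WT DMM library. Neighbouring chromosomes alternate in shade, and the tallest bars, 15 and 13 regions, stand side by side on chromosome 8.

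Mutant cartilage after DMM also differed from wild-type sham cartilage in both directions: 40684 of 71974 changed regions were lower and 31290 were higher (43.5% higher, exact 95% interval 43.1 to 43.8, binomial p = 2.57e-269 across regions). Among the list members with the most changed regions, Sox5 held 23 lower and 5 higher, Nfia 16 and 3, and Col5a1, a chain of type V collagen, 15 and 1. Alpl, the alkaline phosphatase needed for mineralisation, held 6 lower and 1 higher, and Col2a1, the main collagen of cartilage, 4 and 1. In 15289 of the lower regions the MUT DMM mean was 0. The other 25395 had a median fold of 7.06 with the repeated library counted once. The share of higher regions depended on the choice of regions and of test: it was 52.1% without the 25% of regions with the lowest level, and limma called 5934 regions higher and 28276 lower.

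The levels at named regions were as follows. Sox5 stood at 0.370 ± 0.523 (n = 2) in MUT DMM and 12.9 ± 1.37 (n = 3) in sham, and Nfia at 6.20 ± 4.60 against 17.5 ± 3.35. Col2a1 stood at 5.46 ± 5.64 against 11.6 ± 2.18, a difference close to the spread of the 2 MUT DMM libraries. Col27a1, with 4 lower regions and none higher, stood at 5.46 ± 5.64 against 15.7 ± 8.90. The procollagen protease genes Adamts14 (6 lower, 2 higher) and Adamts2 (7 lower, 1 higher) stood at 0.370 ± 0.523 against 11.3 ± 1.68 and at 2.21 ± 3.13 against 19.2 ± 0.586. The region of Alpl on chromosome 4 from 137773301 to 137773580 was at 0 in both MUT DMM libraries and at 13.3 ± 6.46 (n = 3) in sham. Lef1 (8 lower, 3 higher), a Wnt transcription factor, stood at 0.370 ± 0.523 against 12.3 ± 3.19, and Tcf7l1 (10 and 2) at 18.6 ± 0.339 against 46.4 ± 17.4. Smad3, which carries TGF-beta signals to the nucleus, held 8 lower and 2 higher regions, with 50.4 ± 8.84 against 76.5 ± 3.57. Stat3 (4 and 1) stood at 0.370 ± 0.523 against 7.85 ± 1.61. Some named regions were higher in MUT DMM. Runx2 (6 higher, 3 lower) stood at 16.1 ± 9.46 against 5.41 ± 1.98, Il1r1 (3 higher, 2 lower) at 69.2 ± 17.7 against 52.1 ± 5.99, and Cd36 (3 higher), a fatty acid transporter, at 368 ± 26.7 against 243 ± 10.4. Tet2 held 3 higher and 2 lower regions and Tet3 held 1 higher and 5 lower. Further lower and higher counts were 8 and 7 in Ltbp1, 11 and 3 in Igf1r, 10 and 4 in Prkca, 5 and 3 in Dnmt3a, 7 and 5 in Pax5, 5 and 4 in Ebf1, 5 and 7 in Ttn, 7 and 2 in Erg, 4 and 3 in Flt1, 3 and 1 in Pck1, and 6 and 1 in Clic5.

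Fto held the most higher regions (34, with 22 lower), followed by Ptprd (27 and 7), Tenm3 (23 and 12) and Lrp1b (19 and 7). Gse1 held the most lower ones (34, with 3 higher), followed by Camta1 (29 and 10), Wwox (29 and 13) and Ptprn2 (28 and 13). The 3 higher regions of smallest adjusted p all lay on chromosome 8 between 88842321 and 95160680, in Gm42034, outside genes, and in Kifc3. At Kifc3, a kinesin gene, MUT DMM stood at 23.8 ± 6.95 (n = 2) and sham at 0.183 ± 0.318 (n = 3). The lower regions of smallest adjusted p were in Foxn1, in Gm40548 and outside genes on chromosome 13, each at 0 in both MUT DMM libraries, with 11.6 ± 0.935 in sham at Foxn1.

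Of the hypertrophy and ossification list, 24 of 30 genes held a region lower in MUT DMM where length-matched lists gave 16.2 (permutation p = 0.00140, adjusted p = 0.0392). Examples were Ank with 6 lower regions, Hdac4 with 5 and the hedgehog receptor gene Ptch1 with 4. The call was lost with a 5 kb margin around genes and among regions that separate the libraries. Higher regions lay in 14 of the same 30 genes. In the order higher then lower, the remaining lists had 11 and 18 of 30 cartilage matrix genes, 15 and 17 of 33 protease genes, 21 and 20 of 28 chondrogenic transcription factors, and 22 and 33 of 48 Wnt genes. There were 20 and 31 of 43 TGF-beta and BMP genes, 24 and 28 of 39 insulin, IGF and mTOR genes, 12 and 26 of 46 inflammatory genes, and 7 and 16 of 22 genes of the methylation machinery. Cell markers were 11 and 18 of 32 haematopoietic, 13 and 17 of 28 skeletal muscle, 11 and 14 of 20 endothelial, 7 and 2 of 15 adipocyte, and 9 and 11 of 20 fibroblast and synovial lining genes. The smallest adjusted p among these was 0.387. Lower regions lay in gene bodies more often than higher ones, 59.4% against 46.3% (Fisher's exact p = 3.94e-265).

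This comparison does not hold the near-empty WT DMM library, which limited separation in the others. Without that library 85.3% of the higher and 31.0% of the lower calls of WT DMM against WT sham separated, also beside 20% by chance. In MUT DMM against WT sham, every distinct MUT DMM library lay beyond every sham library in 59118 regions, 39.8% of them higher in MUT DMM. They are 75.2% of the higher and 87.5% of the lower calls, where chance gives 20% before any choice of regions by p. Chromosome Y held 1940 of the higher and 127 of the lower regions, and the third-listed sham library had few reads there. Without chromosomes X and Y, 67221 regions remained, 42.6% of them higher.

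Regions called in more than 1 comparison were paired by overlap. The comparisons of WT DMM with sham and of MUT DMM with WT DMM shared 7675 pairs of regions, and 6180 of these were higher after DMM in wild-type and lower in the mutant. A further 1082 were lower and then higher, and 319 and 94 moved the same way, which is 5.38% of pairs (odds ratio 0.00448, Fisher's exact test). Sites of this kind lay in Sox5, Runx2, Trps1, Nfia and Ror1, 1 region in each, and 2 in Lgr4, while the gene with the most, Sfi1 with 16, has near-identical copies. Both comparisons use the WT DMM libraries with opposite sign. Unchanged groups simulated with the read steps of these libraries gave 0% of pairs in the same direction, so opposite signs can arise with no effect at all. The simulation chose regions by fold and set a small spread between libraries, so its percentages here and below are a rough guide only. Shuffled positions gave 567 pairs.

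MUT DMM against WT DMM and MUT DMM against WT sham shared 13121 pairs, of which 88.4% had the same direction, 5785 higher and 5820 lower in both (odds ratio 66.6, Fisher's exact test). Simulated unchanged groups gave 99.8% and shuffled positions gave 975 pairs. WT DMM against WT sham and MUT DMM against WT sham shared 3686 pairs, of which 50.8% had the same direction (odds ratio 1.43, Fisher's exact p = 1.11e-06), beside 73.1% from simulated unchanged groups and 611 pairs from shuffled positions. Each pair of comparisons has a group of libraries in common that is too small to be divided, so these pairs do not separate an effect from the shared libraries.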

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

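Tests chosen only after the data had been seen were limma with its own settings, every region as listed, separation of all distinct libraries with or without the near-empty one, gene bodies with 2 kb either side, the gene lists from separated regions, and leaving out X and Y or the bins of regions read in MUT DMM only. Over 21 results, 116 of 142 alternatives kept the direction and stayed within 1.5 times the value, 22 moved further and 4 reversed, and the cause was not tested unless a value given here shows it. Keeping 1 row per position could change nothing, since no position was listed more than once. Outside limma, leaving out a library made no new calls and only asked whether called regions kept the sign of their difference. Such alternatives are in the tally, so it is no measure of how robust the calls are. Requiring all distinct libraries to separate left 1172 changed regions in WT DMM against WT sham, of which 36.8% were higher, and 27328 in MUT DMM against WT DMM, of which 55.3% were higher. Both shares reversed by construction, because the near-empty library was at 0 in 97.5004% of the higher regions of the former and 61.8% of the lower regions of the latter, and without it the shares were 97.52% and 31.3%. Limma called 7 regions in the former, all lower (361 at unadjusted p under 0.05), fewer than the 107 unchanged regions it called in the simulation with that library, 0 in the latter (2869 at unadjusted p under 0.05, beside the 65249 of the authors' test) and 34210 in MUT DMM against WT sham, 5934 of them higher. Without the near-empty first-listed WT DMM library limma called 33733 (32922 higher, 811 lower) and 10373 (3854 higher, 6519 lower) regions in the comparisons that hold it, and without the third-listed one 553, all lower, and 0. Leaving out any other library gave 7 to 44 calls in WT DMM against WT sham, 0 to 108 in MUT DMM against WT DMM, and 20630 to 50662 in MUT DMM against WT sham. The share of higher regions in MUT DMM against WT DMM ranged from 33.8% to 53.5% when each library was left out, the last value without the third-listed WT DMM library. It was 45.9% when the 25% of regions with the lowest level were left out. The same step in MUT DMM against WT sham gave 52.1%. With random lists not matched on length, 4, 9 and 8 list calls were made in WT DMM against WT sham, MUT DMM against WT DMM and MUT DMM against WT sham, where matched lists gave 0, 2 and 1. The simulated lists of long genes gave 26.0% false calls without matching. That simulation made regions more frequent in long genes, so it shows that length can give such calls, not that it gave these. From separated regions alone, taken without the near-empty library, 1 list call was left in MUT DMM against WT DMM. In MUT DMM against WT sham separated regions left 0, and a margin of 5 kb also left 0. With a log2 fold change of at least 1 in both comparisons, shared pairs were 6309 of 13121 between the comparisons with MUT DMM and 2154 of 3686 between the comparisons with WT sham. Gene-body differences kept their direction under each alternative tried. No paired analysis was possible because the columns carry no replicate numbers. The planned comparisons of TMM with DESeq2 size factors, of edgeR with DESeq2 and of filters on low counts were meant for raw counts and were not run. Depth limited single levels in both directions: the shallower MUT DMM library was at 0 in 75.6% of the lower regions of MUT DMM against WT sham, where its single read was worth 9.45 normalized counts.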

Other observations

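The tests were chosen only after the result was seen, except those of developmental gene families, of the repeated library and of other splits of the libraries. Developmental transcription factors differed from genes of their length in some directions only. Among genes of homeobox, paired box, T-box and related families (Hox, Pax, Lhx, Tbx, Nkx, Irx, Dlx and sine oculis genes), 59 held a region higher in MUT DMM than in WT DMM, where length-matched lists gave 31.5 (23 to 41, permutation p = 0.0002, the smallest possible, adjusted p = 0.0006), and 26 held a lower one against 29.2 (adjusted p = 0.638). Against WT sham, 41 of them held a higher region in MUT DMM against 23.2 in matched lists (adjusted p = 0.0006), and 43 held a lower one against 32.5 (adjusted p = 0.0345). In wild-type cartilage after DMM, 13 of these genes held a region lower than in sham against 4.59 (adjusted p = 0.00160), while 21 held a higher one against 21.1. A hypothesis is that the excess of Wnt genes with higher regions in MUT DMM may belong to developmental regulator genes generally and not to that pathway. The 59 genes of these families go with it. Against WT sham, where the families again held an excess of higher regions, 22 of 48 Wnt genes held one beside 21.9 in matched lists. The Wnt list thus did not follow the families there. Lists were not matched on CCGG sites, so a richness in such sites stays open for both.

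The sex chromosomes and a coat colour gene gave further differences. On autosomes, WT DMM against WT sham had 14.4 to 19.2 higher regions per Mb, and chromosome X had 4.11. In MUT DMM against WT sham, lower regions on autosomes ranged from 11.1 per Mb on chromosome 3 to 20.4 on chromosome 11, beside 11.5 on X and 1.398 on Y. At a (nonagouti, chromosome 2 from 155014881 to 155015200), where laboratory strains carry different alleles, the sham libraries had 378, 64 and 10 reads and the WT DMM libraries 0, 4 and 4. In normalized counts these were 121, 45.8 and 1.71 in sham and 0, 5.34 and 4.17 in WT DMM. The third-listed sham library thus lay within the range of WT DMM. In the overlapping region of MUT DMM against WT DMM, the MUT DMM libraries had 278 and 7 reads. At Tmem267, chromosome 13 from 119488221 to 119488600, WT DMM had 2, 17 and 18 reads and sham had 313, 29 and 1081. In normalized counts these were 31.4, 22.7 and 18.7 in WT DMM and 100, 20.7 and 185 in sham. The second-listed sham library thus lay within the range of WT DMM.

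Nearly every changed region of WT DMM against WT sham was higher. The near-empty WT DMM library was at 0 in 97.5004% of the higher regions and so had no reads to raise their mean, and 85.3% were higher in both other WT DMM libraries than in every sham library, but its part in the calls stays open, since the regions were chosen with it. Its part in the lower calls stays open too: 31.0% were lower in both other WT DMM libraries than in every sham library, while 91.6% kept a lower mean without it. An even low background in the WT DMM libraries, or in sham for the lower regions of MUT DMM against WT sham, was not decided by shares in gene bodies 2.104 and 12.7 percentage points above that of autosomal bases, because a background would follow CCGG sites and not bases. Of the 10 splits of the 6 libraries only the real split, 1 of 10, gave 7 limma calls, with 4 as the highest of the others, and 10 splits are too few for a share under 0.05. At unadjusted p under 0.05 the real split gave 361 regions, and the split that puts the near-empty library with the first- and third-listed sham libraries gave 16275. That count shows no further structure of the libraries, because the regions were chosen in these libraries and the near-empty one was at 0 in nearly all higher ones. The operation, the biological difference between the groups, was not separable from the explanations in this paragraph.

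Regions read in MUT DMM and in no WT DMM library lay together on a few chromosomes. Chance zeros at low depth are argued against by the fullest bin, which held 15 of them where the highest of 1000 equal draws from the higher regions gave 6. Regions in these bins differed in sham, so they do not form a single pattern. At chromosome 8 from 91752441 to 91752860 MUT DMM had 60 and 4 reads, and no WT DMM or sham library had any. In a on chromosome 2, at the region starting at 155020341, MUT DMM had 112 and 6 reads, WT DMM 0, 0 and 2, and sham 163, 22 and 7. Stretches of another strain's sequence, carried by one group of this mixed strain, might place such regions together. Regions at least 5 times lower in MUT DMM, with 10 or more normalized counts in WT DMM, made up 7.14% of the lower regions in the chromosome 8 bins and 4.48% elsewhere (Fisher's exact p = 0.0720), which leaves this open. For regions 5 times higher the shares were 30.2% and 4.75%, which is no test, because the bins were picked for such regions.

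The third-listed sham library had few reads on chromosome Y. Its median there was 0.550 normalized counts in MUT DMM against WT sham, 2.5% of the lower of the other sham libraries (25.4 and 22.0), and its share of reads on X was 4.97% against 3.48% and 3.54%, with an X median of 11.65 against 9.54 and 11.58. In WT DMM against WT sham its Y median was 2.73 against 7.05 and 7.15, and its X median, 5.47 against 6.09 and 6.44, was the lowest of the sham libraries. Its share of reads on X was nevertheless the highest of them there too, 8.86% against 5.72% and 4.56%. Its share on Y was the lowest, 0.563% against 1.18% and 0.998%. Low depth is argued against, since it was the deepest of the sham libraries with 7.86 M reads. A library from an animal without a Y chromosome, or with its label mixed up, stays open, since the tables differ in how low Y was and 96192 reads of it were still there, and the labels say that all mice were male. No biological explanation was tested.

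The repeated MUT DMM library entered the authors' tables as if it were a pair of replicates, and limma calls with it counted once were 80.3% of those with it as deposited in MUT DMM against WT sham, with 0 calls in either way in MUT DMM against WT DMM (2869 and 10222 at unadjusted p under 0.05).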
